A study of Rattus norvegicus with 28 samples.

How the data were processed

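The samples were total RNA of rat soleus, extracted from pooled 25 µm cryosections of the muscle with RNeasy chemistry, per the labels' protocols. Per the labels, 3 µg of RNA was reverse-transcribed with the primer mix of the Clontech Atlas Rat 1.2 array and P32 label, so each array has 1 colour. The deposited value table holds 1185 spots on 28 arrays. Its unit is hybridisation intensity on a linear scale, deposited as a share of the array: the values of every array sum to 1. No value is 0 or below, and the lowest value of every array lies well above 0, so that background does not seem to have been subtracted. Image quantification, background treatment and any further transformation are not given in the sources used here. Because each array sums to 1, a large change of a bright spot shifts the shares of the others. Direction needs no choice of dye, and values are printed as ppm, 1e+06 times the share.

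Groups were taken from the sample titles: control, suspended, control with ALCAR and suspended with ALCAR, 7 arrays each. The labels name rats but do not state how many animals gave each RNA; if arrays shared animals, the p-values would measure only the spread between these samples. No labels name a batch, slide or date. The array pair that was most alike (ALCAR control N and Q) had a Spearman rho of 0.948 and 0 identical values, so no array was treated as a copy.

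Shares were transformed as log2(share + c), with c the lower quartile of all values, 335 ppm. Array medians differed 2.16-fold, above the limit of 1.5-fold fixed before the data were examined, so the log2 values were quantile normalised between arrays. A filter for spots above 0 in at least 7 arrays removed 0 spots. A linear model with a mean per group was fitted over all 28 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method over the 1185 spots of a comparison; changed means an adjusted p under 0.05. All limma tests and permutation tests were two-sided. Intervals of 95% come from the moderated standard error, which rests on 1 spread per spot over all 4 groups. Where the groups differ in spread, it can be too small or too large for a comparison. Exact permutation tests of single spots compared the normalised log2 values of 7 against 7 arrays, and their p-values were not adjusted over the 1185 spots. A spot picked by its limma p in a comparison is likely to have a small exact p there. Fold values of means are ratios of mean shares, without normalisation and without subtracting the floor, so they understate changes of dim spots. Correlations are across spots, and their p-values come from 100 relabellings of the arrays. Figures were drawn with matplotlib 3.10.9.

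The spot numbers, 702 beginning with R and 483 with RG, matched 0 entries of the gene table at hand, so that no gene is named and the 22 gene lists fixed beforehand were not tested. The rule fixed for named items (the smallest p among probes with a gene symbol, in each direction) could not be applied as written. In its place the 2 changed spots with the smallest p in each direction are named for suspended against control and for ALCAR suspended against suspended, and the 1 spot that changed in ALCAR control against control.

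The model was tested on simulated data with 200 of the 493 brighter spots changed above the floor, 10 times per comparison over 1185 spots. For suspended against control 5.4% of calls were false, and 13.6% of simulated log2 changes of 0.5, 56.6% of changes of 1 and 87.6% of changes of 2 were recovered. For ALCAR suspended against suspended 7.0% of calls were false and 55.8% of log2 changes of 1 were recovered. For ALCAR control against control 8.1% of calls were false, the highest share of the 6 comparisons, and 55% of log2 changes of 1 were recovered. For the interaction 4.8% of calls were false and 20.2% of log2 changes of 1 were recovered. A simulated change of 1 was estimated at a median of 0.347 for suspended against control, since the floor and the pseudocount shrink it. The noise was drawn apart for each spot, with the same spread in every group and no outlying arrays. The false shares therefore need not hold for the real arrays. Random splits of those called up to 39 spots for suspended against control and 23 for ALCAR control against control. Dim spots were not changed, yet 52 spots called in suspended against control were not above 2 times the average floor.

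Alternatives fixed beforehand were a pseudocount of a 10th of c or 4 times c, no normalisation, centring each array on the spots above the upper quartile, the spots above the median of mean signal, eBayes without trend or with a robust prior, only the groups compared in the fit, limma array weights, leaving out each array, an adjusted p under 0.10, and the shared rat numbers as a block. Added after the data were seen were subtraction of each array's 5th percentile, leaving out the 5 arrays with an array weight under 0.5 (control 9, control 10, suspended 5, ALCAR control O and ALCAR suspended H), the array's log2 median share as a covariate, leaving out suspended 4 and 5 or control 2 and 4 (far out on the principal components), the 10 arrays of the block without it, and correlations by rank and without the 2 farthest spots.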

Results

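RNA of the soleus, a slow postural muscle of the lower leg that wastes when it is no longer loaded, was profiled in 3-month-old female Wistar rats by hybridising P32-labelled cDNA to cDNA arrays of 1185 spots. The 28 arrays fell into 4 groups of 7. Control rats were kept in cages. Suspended rats had their hindlimbs unloaded by suspension for 14 days, a ground model of weightlessness. A control group and a suspended group received acetyl-L-carnitine (ALCAR), the acetyl ester of the carrier that takes fatty acids into mitochondria, and are called ALCAR control and ALCAR suspended here. The design text lists 21 samples in 3 groups, and the ALCAR control group appears in the sample labels alone. The dose, route and duration of ALCAR are not given in the labels, nor is a number of days for the ALCAR control rats.

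Each value was a spot's share of the summed signal of its array, given here as ppm (1e+06 times the share). The array medians lay between 283 and 613 ppm. The 5th percentile of an array, taken as its floor, averaged 319 ± 57.4 ppm in control, 282 ± 66.8 ppm in suspended, 285 ± 112 ppm in ALCAR control and 315 ± 99.2 ppm in ALCAR suspended arrays (mean ± SD, n = 7 each). Most of the array therefore lay close to the floor: 292 of the 1185 spots had a mean above 2 times the average floor of 300.3 ppm. The 10 brightest spots of each array held 19.9 ± 4.91% of the signal in control, 24.9 ± 4.76% in suspended, 25.2 ± 6.42% in ALCAR control and 22.9 ± 5.70% in ALCAR suspended arrays (SD, n = 7). Over 25 exact permutation tests of such array measures between groups, the smallest p was 0.0804, for the share of the 10 brightest spots in suspended against control arrays, with a Benjamini-Hochberg adjusted p of 0.799. The number of arrays limits the precision of every value. The files do not pair the spot numbers with genes, so spots are named by number. The labels name no batch. The untreated rats are named by numbers and the rats of both ALCAR groups by letters, so any difference in handling between these sets would coincide with ALCAR.

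The first comparison asks what 14 days of unloading did to the soleus of untreated rats. An abundant transcript, at spot R150, lost most of its signal: it stood at 11486 ± 5046 ppm in control and at 2444 ± 1163 ppm in suspended muscle (SD, n = 7 each), 4.70-fold lower by the means. The opposite move was found at R367, one of the brightest spots of the array, which rose from 9415 ± 1933 to 23449 ± 14282 ppm, 2.49-fold. RG334 rose from 359.6 ± 59.0 ppm, close to the floor, to 1049.9 ± 549 ppm. R303 fell from 614 ± 74.8 to 363 ± 83.6 ppm. For R150, R367 and R303 the 7 suspended and 7 control arrays did not overlap after normalisation, and for RG334 47 of the 49 pairs of arrays went the same way.

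On the log2(share + pseudocount) scale, which understates changes of dim spots, R150 differed by −2.06 (SE 0.27, 95% interval −2.61 to −1.50, limma adjusted p 2.12e-05). R367 differed by 1.02 (SE 0.16, limma adjusted p 0.000216) and RG334 by 0.93 (SE 0.16, limma adjusted p 0.000582). R303 differed by −0.40 (SE 0.062, limma adjusted p 0.000216). The pseudocount sets the size for the dimmer spots: with a 10th of it and with 4 times it RG334 differed by 1.36 and 0.47, and R303 by −0.65 and −0.18. The exact permutation p of R150, of R367 and of R303 was 0.000583, the smallest that 7 against 7 arrays can give, and that of RG334 was 0.00175. These exact p-values are unadjusted, and the spots were picked by their limma p in the same arrays, so they add no separate evidence. In all, 72 of 1185 spots changed at an adjusted p under 0.05, 31 of them higher and 41 lower in suspended muscle. Their median difference was 0.33 on the log2 scale, and 7 changed 2-fold or more on that scale. Of the 72 spots, 20 were among the 292 brighter ones, 9 higher and 11 lower. The count depended on the processing: it was 20 without normalisation between arrays, 20 with arrays centred on their bright spots, 24 with these 14 arrays fitted alone, 149 with arrays weighted by quality and 151 without the 5 arrays of lowest weight. Without control 2 and 4, which lay far out on the first principal component, it was 37, 10 higher and 27 lower.

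**Figure D1:**
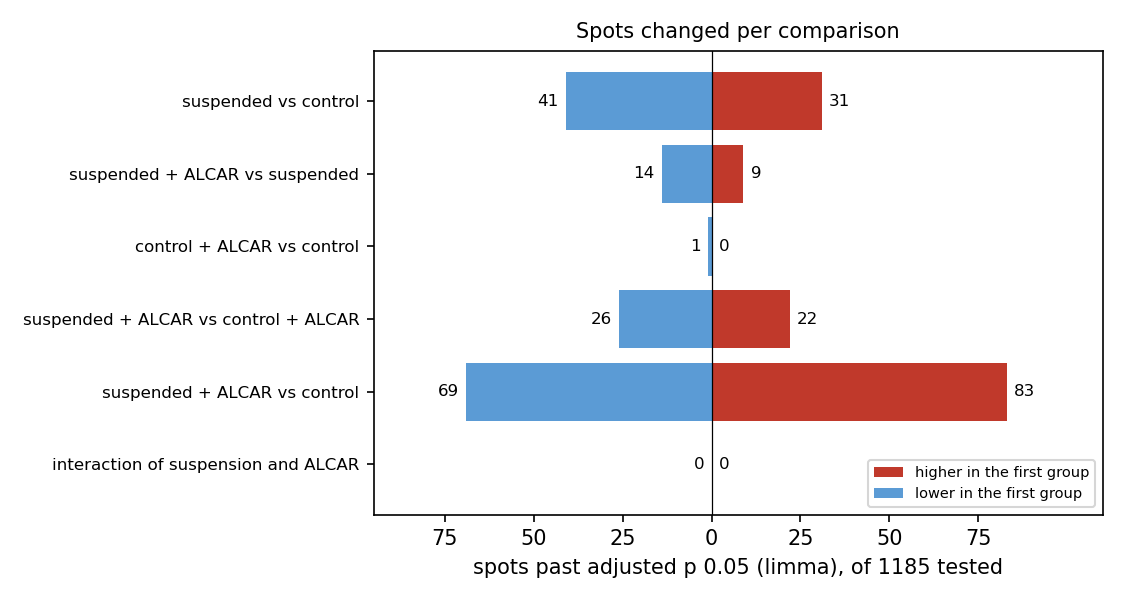
Number of spots higher (right, red) and lower (left, blue) in the first-named group of each comparison, out of 1185 tested, at a limma adjusted p under 0.05 with 7 arrays per group. Suspension changed 72 spots without and 48 with ALCAR, ALCAR changed 23 spots in suspended and 1 in control muscle, and 0 spots passed the test of the interaction.

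**Figure D2:**
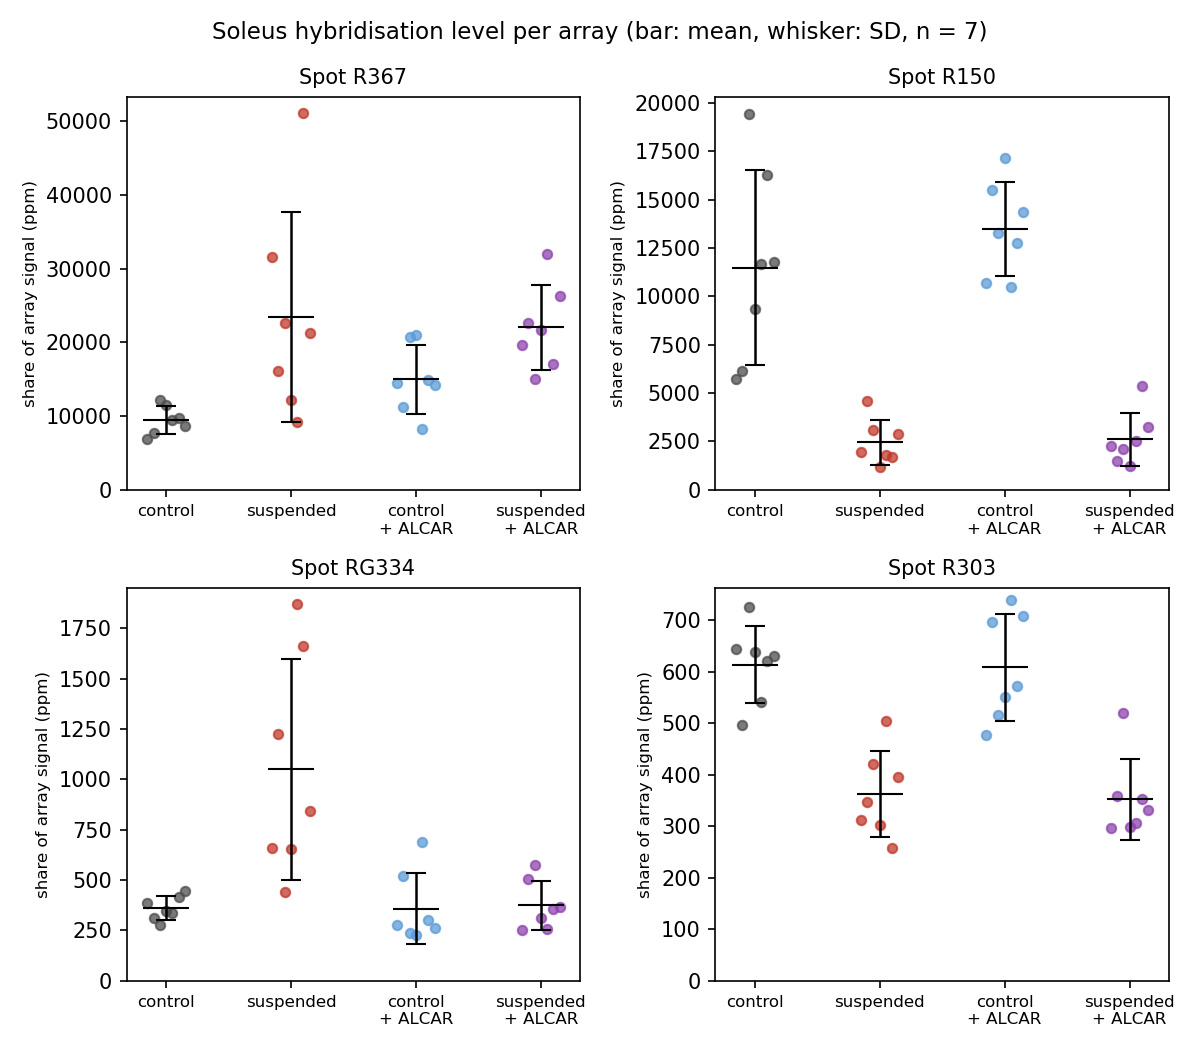
Share of the array signal (ppm, linear axis from 0) of the spots R367, R150, RG334 and R303 in each of the 28 arrays, as points by group, with the group mean (long bar) and SD (whiskers, n = 7). R150 and R303 were lower in both suspended groups, R367 was higher in both, and RG334 was high in suspended rats without ALCAR, at 1049.9 ppm, and between 357 and 374 ppm in the other groups.

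The second comparison asks what ALCAR did in unloaded muscle. The rise of RG334 seen with suspension was not there in ALCAR suspended rats: the spot stood at 374 ± 123 ppm in ALCAR suspended against 1049.9 ± 549 ppm in suspended muscle (SD, n = 7 each), 2.81-fold lower by the means, and at 359.6 ppm in control muscle. RG360 was at 382 ± 98.7 ppm in ALCAR suspended, 632 ± 180.3 ppm in suspended and 393 ± 65.8 ppm in control muscle, and its rise with suspension (log2 difference 0.44, limma adjusted p 0.000999) did not pass without normalisation (0.085) or with centring on bright spots (0.0518). In the opposite direction, RG498 was at 379.6 ± 122 ppm in ALCAR suspended and 283 ± 63.9 ppm in suspended muscle, and R714 at 383 ± 113 and 296 ± 64.9 ppm. In suspended arrays, whose floor averaged 282 ppm, neither spot stood clear of the floor, and their ranges in ppm overlapped between the groups.

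After normalisation RG334 differed by −0.87 (SE 0.16) and RG360 by −0.43 (SE 0.082), each with a limma adjusted p of 0.00459 and an exact permutation p of 0.00408, and in 43 of 49 pairs of arrays. The model takes 1 spread per spot for all groups, but both spots varied far more in suspended arrays. Their SD on the log2 scale was 0.65 and 0.28 there, against 0.085 and 0.066 in ALCAR suspended arrays. With these groups fitted alone their SE was 0.21 and 0.098. RG498 was higher by 0.16 (SE 0.030, limma adjusted p 0.00459) and R714 by 0.14 (SE 0.030, limma adjusted p 0.00795), in 48 of 49 pairs each, with an exact permutation p of 0.00117 each. Here too the 4 spots were picked by their limma p in these arrays, and the exact p-values are unadjusted. In all, 23 spots changed, 9 higher and 14 lower with ALCAR, with a median difference of 0.25. Leaving out 1 array moved that count to between 8 (without ALCAR suspended H) and 58 (without suspended 2), and 12 of the 28 arrays moved it by over 1.5 times. None of the 23 changed 2-fold on the log2(share + pseudocount) scale (RG334 differed by −1.25 with a 10th of the pseudocount and by −0.45 with 4 times it), and 3 of them, all higher, were among the 292 brighter spots. The bright spots R150 and R367 did not pass the test: R150 was at 2593 ± 1379.9 ppm in ALCAR suspended muscle, with a log2 difference of 0.11 (95% interval −0.45 to 0.66), and R367 at 22021 ± 5746 ppm, with 0.06 (−0.27 to 0.39). With the suspended and ALCAR suspended arrays fitted alone 0 spots passed limma's test (245 at an unadjusted p under 0.05), and the 4 spots named then had an adjusted p of 0.0638 (for RG334, 2.53e-05 to 0.0638 over all alternatives). Without normalisation between arrays, and with arrays centred on their bright spots, 2 spots passed, both lower with ALCAR and RG334 among them, against 94 with arrays weighted by quality. RG360 (adjusted p 0.190 and 0.208), RG498 (0.861 and 0.997) and R714 (0.902 and 0.997) did not pass under these 2 scalings. Their standard errors rose there, while the differences stayed about as large: −0.42 and −0.45 for RG360, 0.20 and 0.17 for RG498, 0.18 and 0.15 for R714. Without suspended 4 and 5, far out on the second principal component, 13 spots passed, 8 of them among the 23.

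Of the 31 spots that rose with suspension, 7 fell with ALCAR in suspended rats, among them RG334 and RG360, and 0 of the 41 that fell with suspension rose with ALCAR. Independent lists of these sizes would share 0.366 spots in the first case and 0.311 in the second. Both comparisons use the same 7 suspended arrays with opposite sign, which gives opposed differences by chance alone. Across all 1185 spots, which are not independent replicates, suspended minus control and ALCAR suspended minus suspended correlated at r = −0.33, while relabelled arrays with no effect gave −0.51 on average, with −0.81 to −0.09 as their middle 95%. The covariance was −0.0100 against −0.00729 on average for residuals with no effect, a difference of −0.00272. It lay inside the middle 95% of those residuals, −0.0161 to −0.000334. With the suspended arrays split into parts of 3 and 4, with 1 part for each comparison, the mean r over 100 splits was −0.032 and the covariance −0.000508. The middle 95% of relabelled arrays spanned −0.41 to 0.31 for that r (permutation p 0.931).

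The third comparison asks what ALCAR did in muscle that stayed loaded. R700 was the 1 spot of 1185 that passed, and it is named for that reason, after its values were seen. It stood at 349.8 ± 113 ppm in ALCAR control and 521 ± 57.8 ppm in control muscle (SD, n = 7 each), 1.49-fold lower, with a log2 difference of −0.23 (SE 0.042, limma adjusted p 0.00636, exact permutation p 0.000583). This ALCAR control difference did not pass without normalisation (limma adjusted p 0.238) or with centring on bright spots (0.581). It passed with ALCAR control and control arrays fitted alone (0.0486). R700 was also lower in suspended muscle, at 382 ± 90.7 ppm, a log2 difference of −0.19 from control (limma adjusted p 0.00512). Between suspended and control muscle it did not pass without normalisation (limma adjusted p 0.220), with centring on bright spots (0.448) or with these groups fitted alone (0.0597). The differences in these settings, −0.26, −0.22 and −0.19, were no smaller. In ALCAR suspended muscle R700 was at 386 ± 104 ppm, a log2 difference of −0.21 from control (limma adjusted p 0.00193, 49 of 49 pairs). That difference did not pass without normalisation (0.189) or with centring (0.268). R700 was thus lower than control in each of the other 3 groups, and its change does not single out ALCAR. The 3 comparisons share the 7 control arrays, and R700 was picked by its difference from them. High values in those arrays alone could give this agreement. Among the spots that changed with ALCAR in suspended rats, RG334 stood at 357 ± 177 ppm in ALCAR control and RG360 at 369 ± 173 ppm, and neither passed, with log2 differences from control of 0.08 (95% interval −0.26 to 0.41) and 0.05 (−0.12 to 0.22). In this comparison 182 spots had an unadjusted p under 0.05, and other splits of the same arrays gave up to 237. The count of 1 moved to 0 without normalisation and with centring on bright spots (limma; 124 and 78 spots at an unadjusted p under 0.05), and to 43 with weighted arrays (12 higher, 31 lower) or without the 5 arrays of lowest weight (8 higher, 35 lower). With the array's median share as a covariate it was 59, and the balance turned to 45 higher and 14 lower, so the direction depends on the setting. The count was 10 without suspended 4 and 5 and 15 without suspended 5, the most that leaving out 1 array gave.

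Suspension was also compared within the ALCAR rats. R150 again lost most of its signal, from 13468 ± 2439.7 ppm in ALCAR control to 2593 ± 1379.9 ppm in ALCAR suspended muscle (SD, n = 7 each), 5.19-fold lower by the means. R303 fell from 609 ± 104 to 352 ± 78.5 ppm, and R367 rose from 14947 ± 4679.7 to 22021 ± 5746 ppm. RG334 did not pass, at 357 and 374 ppm, with a log2 difference of −0.02 (95% interval −0.35 to 0.31). The log2 differences were −2.15 for R150 (SE 0.27, limma adjusted p 4.18e-06), −0.54 for R303 (SE 0.062, limma adjusted p 9.40e-07) and 0.64 for R367 (SE 0.16, limma adjusted p 0.0153). In all, 48 spots changed, 22 higher and 26 lower. Without normalisation 19 changed, 6 higher and 13 lower, and with centring on bright spots 16, 3 higher and 13 lower; R367 did not pass in either (adjusted p 0.543 and 0.785) nor without the 5 arrays of lowest weight (0.0526; 0.00894 to 0.785 over all alternatives).

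The effects of suspension with and without ALCAR come from separate arrays. Of the 72 spots that changed without ALCAR, 61 went in the same direction with ALCAR, and 12 passed in both, 2 higher and 10 lower, where independent lists would share 0.576 and 0.900. The lists are not fully independent: both tests use the same estimate of spread per spot, and spots vary together. Chance sharing can therefore be larger, and no relabelled range was drawn for the 61 or the 12. The median difference of these 72 spots, signed by the call, was 0.33 without and 0.09 with ALCAR, and that of the 48 spots called with ALCAR was 0.31 with and 0.11 without it. Spots picked in 1 comparison show larger differences there by selection alone. Of the 72 spots, 32 had an unadjusted interaction p under 0.05, and 0 passed limma's test after adjustment over all spots. Across the 1185 spots the 2 sets of differences correlated at r = 0.54, outside the middle 95% of relabelled arrays (−0.40 to 0.42; permutation p 0.0099, the smallest that 100 relabellings can give; adjusted p 0.0297 over 3 correlations). Spearman's rho was 0.293 (permutation p 0.099). Without the 2 spots farthest out r was 0.43, so that a few large changes carried part of the relation. Without the 5 arrays of lowest weight r was 0.50 and no longer passed (permutation p 0.0594). The differences between ALCAR and untreated rats, in suspended and in control animals, correlated at r = 0.13 (permutation p 0.455) and rho = 0.175 (permutation p 0.238).

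**Figure D3:**
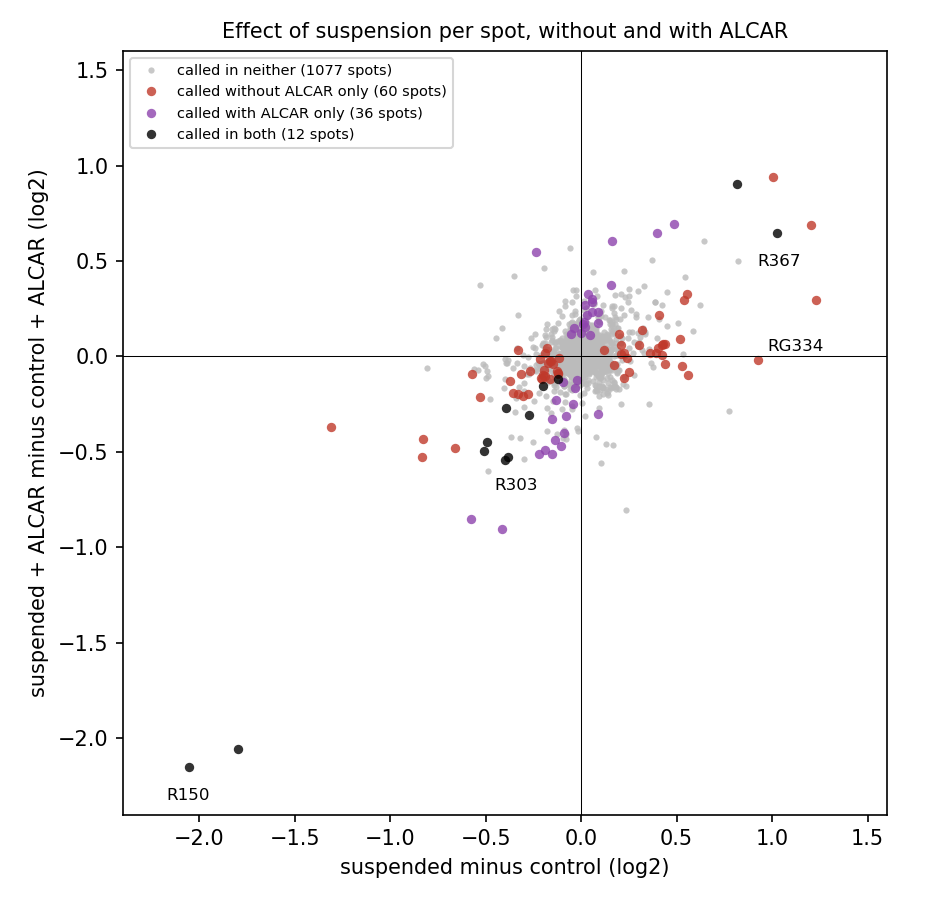
Difference between suspended and control muscle (log2, horizontal) against that between ALCAR suspended and ALCAR control muscle (log2, vertical) for each of the 1185 spots, coloured by the comparison in which the spot passed limma's test (adjusted p under 0.05, 7 arrays per group). The 12 black spots passed in both, with R150 at −2.06 and −2.15, while RG334 lay at 0.93 and −0.02; passing in 1 comparison does not show that the effects differ.

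Whether the effect of suspension differed with ALCAR was tested as an interaction. RG334 had an interaction of −0.95 on the log2 scale (SE 0.23), RG360 of −0.48 (SE 0.12), RG498 of 0.19 (SE 0.043) and R714 of 0.17 (SE 0.042), each with a limma adjusted p of 0.0904. None of the 1185 spots passed limma's test at 0.05, while 169 had an unadjusted p under 0.05. For R150 the interaction was −0.10 (95% interval −0.88 to 0.69). The count of 0 became 24 with weighted arrays and 45 with the array's median share as a covariate.

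ALCAR suspended muscle differed from that of control rats at 152 spots, 83 higher and 69 lower. R150 was at 2593 and 11486 ppm, a log2 difference of −1.95 (SE 0.27, limma adjusted p 3.13e-05), and R303 and R367 also passed, with differences of −0.45 and 1.09. RG334 and RG360 did not pass, with log2 differences of 0.06 (95% interval −0.27 to 0.39) and 0.01 (−0.16 to 0.18). Among the 292 brighter spots 49 changed, 35 higher and 14 lower, and among the other 893 spots 103 changed, 48 higher and 55 lower. Without normalisation 21 spots passed, 7 higher and 14 lower, with centring on bright spots 18, 5 higher and 13 lower, with the spots above the median of mean signal alone 89, and without control 2 and 4 69, 30 higher and 39 lower.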

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

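In each of 60 groups of 7 values (array measures, principal components and named spots), the gap of the highest or lowest array to its neighbour was set against the range of the group. 5 groups had an array farther out than Dixon's 95% limit for 7 values, where chance alone gives about 3. ALCAR suspended I had a score of 1.96 on the second principal component, with the others of its group between −3.06 and −1.31. The gap to the neighbour does not show arrays that stand apart in pairs: on the same component suspended 4 and 5 had scores of 7.16 and 10.4, with the other suspended arrays at −0.64 or below, and on the first component control 2 and 4 had −7.83 and −8.98, with the other control arrays at −5.19 or above. RG334 had a normalised log2 value of −10.32 in control 9, against −10.60 to −10.54 in the other control arrays, and of −10.31 in ALCAR suspended E, against −10.56 to −10.46. R714 was at −10.54 in suspended 2, against −10.64 to −10.60 in the other suspended arrays. RG360 was at −10.16 in ALCAR control O, against −10.51 to −10.43.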

How the results depend on the processing

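Settings added after the data were seen are the floor subtraction, the covariate, the removal of 5 arrays of low weight or of arrays far out on the principal components, and the unblocked 10 arrays. Counts are in the order suspended against control, ALCAR suspended against suspended, ALCAR control against control, ALCAR suspended against ALCAR control, ALCAR suspended against control, and interaction, with limma counts of 72, 23, 1, 48, 152 and 0 as reported. Only counts that moved by over 1.5 times are given; the cause was not tested unless stated. Without normalisation the first 5 counts were 20, 2, 0, 19 and 21, and with centring on bright spots 20, 2, 0, 16 and 18. With the spots above the median alone, ALCAR suspended against suspended, ALCAR control against control and ALCAR suspended against control gave 7, 0 and 89, from fewer spots tested (R700 was not among them). With array weights the 6 were 149, 94, 43, 156, 258 and 24. With only the groups compared, and so fewer arrays, the first 3 were 24, 0 and 4. ALCAR suspended against ALCAR control, which moved by less than 1.5 times, gave 64 in place of 48. The first 2 counts thus fell, while ALCAR control against control and ALCAR suspended against ALCAR control rose. Whether the loss of arrays alone gave the falls was not tested. The standard error moved both ways. For RG334 in ALCAR suspended against suspended it was 0.211 in this fit and 0.164 in the main one. For R367 in ALCAR suspended against ALCAR control it was 0.140 and 0.162. At an adjusted p under 0.10 the 6 were 134, 89, 12, 94, 230 and 9. A pseudocount of a 10th, and subtraction of the floor, each moved ALCAR control against control to 2. Without the 5 arrays suspended against control gave 151 and ALCAR control against control 43. Without suspended 4 and 5, ALCAR suspended against suspended gave 13 and ALCAR control against control 10; without control 2 and 4, suspended against control gave 37 and ALCAR suspended against control 69. With the covariate the first 4 were 123, 73, 59 and 102, and the interaction 45. A higher pseudocount, no trend and a robust prior moved none.

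The numbers shared by 5 control and 5 suspended rats gave no sign of a pairing: same-numbered arrays correlated at −0.0778 to 0.312, and 0 of 5 did so best with their own number. So few arrays cannot exclude a pairing. With the replicate block 4 spots passed, and 4 in the same 10 arrays unblocked.

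Leaving out 1 array gave 51 to 108, 8 to 58, 1 to 15, 39 to 70, 105 to 186 and 0 to 3 spots. ALCAR suspended against suspended gave 40 without control 9, 58 and 41 without suspended 2 and 3, 11 and 12 without suspended 4 and 7, 15 without ALCAR control G or N, and 12, 13, 8, 12 and 11 without ALCAR suspended D, E, H, P and R. ALCAR control against control gave 3, 4, 2 and 6 without control 4, 7, 9 and 10, 2, 15 and 2 without suspended 2, 5 and 6, and 3 without ALCAR suspended I. The interaction was 3 without suspended 3.

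The correlation of the 2 suspension effects was 0.50 without the 5 arrays (permutation p 0.0594, over alternatives 0.0099 to 0.0594), and 0.47 to 0.56 without 1 array. Those of the ALCAR effects (0.06 to 0.20 without 1 array) and of the split comparison (−0.09 to 0.02) stayed inside the relabelled range. Of 874 values of named spots, 845 passed as before, 29 did not pass and 0 reversed. Most of the 874 come from leaving out 1 array, which cost no named spot its call, so all 29 losses fell in the other settings. Most losses came without normalisation and with centring on bright spots. Under each of these scalings RG498, R714, RG360 and R700 lost every call, and R367 its call within the ALCAR rats. Those of R150, RG334 and R303 held there. Leaving all spots in equals the filter used, which removed 0; gene-list tests were not run for lack of gene names. Scaling shifted the median interaction of all spots by up to 0.12, without normalisation. Most spots lay within 2 times the floor, which limits what could be detected.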

Other observations

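R367, one of the brightest spots, stood at 9415 ± 1933 ppm in control and 14947 ± 4679.7 ppm in ALCAR control muscle (SD, n = 7 each). The log2 difference of 0.44 did not pass (limma adjusted p 0.187), though the exact permutation p of this spot alone, chosen after its values were seen, was 0.00758 and 43 of 49 pairs went upwards.

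Of the tests below, the no-effect range of the unsplit correlation was added after its result was seen, and the covariate and the removal of arrays after the data were seen; the others were fixed before their results were seen. The first pattern is the set of 72 spots that changed with suspension. Of 100 splits of the 14 arrays, 1, the real one, gave as many (the highest other gave 39), fewer than the limit fixed beforehand. At an unadjusted p under 0.05 another split gave 274 spots against 268. A random grouping is therefore unlikely by the adjusted count, but 100 splits cannot exclude it. A difference in array background was tested with the array's median share as a covariate, and all 72 spots still passed. That share averaged 423 ppm in suspended and 449 ppm in control arrays (exact permutation p 0.495). With group medians so close the covariate could hardly move the differences, so this result decides little about background. Without control 2 and 4 the count was 37, of which 36 were among the 72. Within the ALCAR rats, 1 of 100 splits gave as many as the real 48 spots (highest other 1). R150 differed by −2.06 in untreated and −2.15 in ALCAR rats, on separate arrays, without overlap in either. A response of the muscle to unloading may account for the pattern, as a hypothesis.

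The second pattern is the set of 23 spots that changed with ALCAR in suspended rats. Again 1 of 100 splits, the real one, gave as many (highest other 11), and all 23 spots passed with the covariate. The covariate could hardly move them, as the median share averaged 427 ppm in ALCAR suspended and 423 ppm in suspended arrays (exact permutation p 0.943). A batch that shifted both ALCAR groups alike would move the same spots in the loaded rats, where they had room to move. Their median difference there, signed by the call, was 0.0185 (95% bootstrap interval −0.020 to 0.062) against 0.25 in suspended rats. The 0.25 is inflated, because the spots were picked by it. The 72 suspension calls likewise fell from 0.33 to 0.09 on separate arrays. Of the 23 spots, 20 were not above 2 times the average floor, among them all 14 lower ones. A shift that lowered such spots could hardly show in loaded rats, as RG334 stood at 359.6 ppm in control muscle. Any ALCAR effect in loaded rats is part of the same difference. The interval puts the median difference in loaded rats below 0.062, but it sets no limit on a batch. A shift in 1 ALCAR group also stays open. The count depends on the fit: it was 0 with the suspended arrays alone and 94 with weighted arrays. An effect of ALCAR on spots raised by unloading, such as RG334, may be present, as a hypothesis to test in new samples.

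The third pattern is the opposed direction of the suspension and ALCAR differences across all spots (r = −0.33). Arrays with no effect gave −0.51 when relabelled (middle 95% −0.81 to −0.09) and −0.50 from residuals, more negative on average than observed. With the suspended arrays split between the comparisons r was −0.032, inside the relabelled range of −0.41 to 0.31. The shared suspended arrays could therefore give the negative r without any reversal. A reversal at single spots such as RG334, or one too weak for 7 arrays to show, stays open.

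For ALCAR control against control, 8 of 100 splits gave at least the real count of 1, and the highest other gave 23, which points to a structure of these arrays whose source was not tested; chance is not excluded. For ALCAR suspended against control 1 of 100 splits, the real one, gave as many as the real 152 (highest other 49). A random grouping is therefore unlikely, though 100 splits cannot exclude it. For the interaction, the real count was 0, which all 100 reassignments of residuals reach by construction (highest other 1), so this count says nothing about chance. At an unadjusted p under 0.05 the real arrays gave 169 spots, and 2 of the 100, the real one included, gave as many (highest other 170).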
